A study of Caenorhabditis elegans with 12 samples.

How the data were processed

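Messenger RNA was measured in 12 libraries of whole early adult *C. elegans*, 3 in each of the 4 groups formed by arrest length and recovery bacteria. Per the labels, 1000 animals per condition recovered at 20 °C, and libraries were made from 500 ng of RNA with 12 PCR cycles and a NEBNext Ultra RNA kit, which keeps no strand. The authors' processing notes name Bowtie 1.1.2, HTSeq 0.12.4 and edgeR without saying which step each served. The genome build and the annotation they used are not given in the sources used here.

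The deposited table holds 12894 genes and 1 signal value per gene and library, made by the authors as counts relative to a scaled library size (CPM). Column sums run from 889133 to 1097908, so the unit is a normalised signal and not plain CPM, in which all sums would be alike. The design written before the data were examined assumed CPM, and its test, limma on log2 values, was kept unchanged. Each column consists of multiples of 1 step, and dividing by that step gave whole reads, with 100% of values within 0.01 read of a whole number and a largest deviation of 0.0001. These recovered reads gave the depth of each library, 21150912 to 30037731 reads over the listed genes, and served 2 alternative tests. They cover the listed genes only, and genes the authors had already removed are unknown. Names were matched for 12723 genes and not for 171. The WBcel235 annotation was used for names and coordinates only.

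Genes with at least 1 CPM in at least 3 libraries were tested, 12830 in all, which removed 64. Values were taken as log2(CPM + 1), where the pseudocount of 1 shrinks changes of genes near or below 1 CPM. The lowest maximum of a listed gene was 1.07 CPM. limma 3.58.1 (R 4.3.3) was fitted with a trend to the 4 groups over all 12 libraries, so that all groups share an estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment within each of the 6 comparisons and a threshold of 0.05. The SE of a change comes from that fit. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so single values rest on the spread shared across genes. Gene list tests used camera with a preset correlation of 0.01 and with an estimated correlation, and fry, which asks whether the genes of a list move one way without comparing them with other genes. Of 35 lists fixed before the data were examined, 33 had the 5 tested members required, giving 198 list tests. A list of mitochondrial genes had no tested member and one of ribosomal RNA genes had 3. No list was chosen from the values of these libraries, and several share members, up to 3 for any pair.

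Named genes were chosen by a rule written before the data were examined. For each of starved EV against control EV, starved *daf-2* RNAi against starved EV and control *daf-2* RNAi against control EV it takes the 10 largest rises and the 10 largest falls. These must be called, have a mean of at least 10 CPM and a gene class symbol, and have all 3 libraries of a group above all 3 of the other. It adds the 5 largest interactions each way, of which none qualified, and from each list up to 4 called members with the largest changes or, with none called, the 2 largest. It always takes *daf-2*, *daf-16*, *sod-3*, *mtl-1*, *fasn-1*, *pod-2*, those of the fat genes that were tested, the vitellogenins and *col-19*. Of the 253 genes so named, 60 have an exon that overlaps an exon of another gene, which for 40 is protein-coding, and reads there cannot be assigned by strand. Reads of close paralogs, such as *pud-1.1* and *pud-1.2*, *vit-3* and *vit-4*, or the major sperm proteins, may not be separable either, since the multi-mapping setting is not known.

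Whether the replicate letters pair the libraries was checked from the deviations of libraries from their group means. For the RNAi comparisons, correlations of same-lettered libraries were 0.821, 0.596 and 0.593 (starved, letters A, B and C) and 0.695, 0.55 and 0.541 (control), so the letters pair these libraries, as a finding from the data and not from the labels. The blocked value is given beside an RNAi result where it changes the call or moves a count by over 1.5 times. Across arrest lengths same-lettered libraries correlated at 0.645, 0.085 and 0.659 on EV and at 0.487, -0.095 and 0.579 on *daf-2* RNAi (letters A, B and C). Letters A and C thus went together and letter B did not, so comparisons across arrest lengths were fitted without the block. Their blocked counts of genes are given too. Within groups, log2 values correlated at 0.973 to 0.994, and pairs of replicates differed with a chi-square of 17.7 to 221 per gene, more than counting error gives, so no library is a copy of another of its group. Libraries of different groups were not compared in this way.

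The fit was tested on simulated data with 12830 genes, of which 200 were changed. For starved EV against control EV it called 11.9%, 65.7% and 98.5% of genes changed by 1.5, 2 and 4 times, with 6 false among 125 calls. For the interaction it called 0%, 14.9% and 87.9%, with 6 false among 74 calls. A missing interaction call therefore says little about differences of 2 times or less. The alternatives were pseudocounts of 0.25 and 4, no filter and a mean of at least 5 CPM, median-of-ratios and quantile scaling, the replicate letter as a block, fits of the compared groups alone, limma array weights, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered reads, and leaving out each library. A block within each arrest length, leaving out all libraries of a letter, and part of the list tests were added after the data were seen. All 12 libraries and all per-sample columns of the table were used.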

Results

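The series measured messenger RNA in whole early adult *Caenorhabditis elegans* of the wild-type strain N2 by sequencing of 12 libraries. Newly hatched larvae were held without food in L1 arrest, the halt in development that hatchlings enter when no food is present, for 1 day (control) or 8 days (starved). They then recovered on bacteria carrying an empty vector (EV) or a vector for RNA interference against *daf-2*, the gene of the insulin/IGF receptor, until eggs appeared. Each of the 4 combinations has 3 libraries with the replicate letters A, B and C. The libraries labelled *daf-2* RNAi are named by that label. Recovery lasted about 52 hours after 1 day and about 68 hours after 8 days of arrest, so arrest length and recovery time cannot be told apart. The comparisons ask what a long arrest leaves in the adult and what *daf-2* RNAi during recovery does to it.

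The deposited table lists 12894 genes, of which 12830 were tested. Reads over the listed genes averaged 23291870 ± 2266794 (SD, n = 3) in control EV and 28138237 ± 1870578 in control *daf-2* RNAi libraries. In starved EV libraries they averaged 24065568 ± 1129023, and in starved *daf-2* RNAi libraries 24403083 ± 3575429. The lowest library had 21150912 reads and the highest 30037731. Levels are given as CPM, the deposited normalised read counts, mean ± SD over the 3 libraries of a group, and changes as log2 differences with limma's adjusted p. Coordinates are those of the WBcel235 assembly.

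The level of *daf-2* (Y55D5A.5, chromosome III, 2994514 to 3040846) in CPM was higher, not lower, in the library labelled *daf-2* RNAi in each of the 6 pairs matched by letter. In control animals *daf-2* went from 188 CPM on EV to 317 on *daf-2* RNAi in pair A, from 155 to 202 in pair B and from 91.6 to 118 in pair C. In starved animals it went from 193 to 706 in pair A, from 153 to 289 in pair B and from 102 to 111 in pair C. The change was 0.96 ± 0.55 (log2, SE) in starved animals (limma, adjusted p = 0.212, or 0.0079 with the replicate letter as a block) and 0.50 ± 0.55 in controls (adjusted p = 0.917). Recovered *daf-2* reads, before scaling, were fewer under the RNAi label in starved pair C (2551 against 2751). Every direction reported for the libraries labelled *daf-2* RNAi follows the labels. *daf-16*, the transcription factor that acts after the receptor, lay at 163 ± 27.7 CPM in control EV and 161 ± 8.31 in control *daf-2* RNAi libraries, at 179 ± 37 in starved EV and 175 ± 15.9 in starved *daf-2* RNAi libraries, and was called in none of the comparisons.

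The DAF-16 targets *sod-3* and *mtl-1* separated the labels. *sod-3* (C08A9.1, X, 17092753 to 17094306), a manganese superoxide dismutase, rose from 1.94 ± 0.39 CPM in control EV to 11.03 ± 1.52 in control *daf-2* RNAi libraries and from 3.52 ± 0.80 to 12.1 ± 2.51 CPM in starved animals. It was 4.24, 7.47 and 5.97 times as high in the RNAi library in control pairs A, B and C, and 3.24, 3.65 and 3.43 times in the starved pairs. The exons of *sod-3* overlap those of C08A9.3 and *lido-1* by 65 and 24 bases, and an unstranded library cannot separate them. The metallothionein gene *mtl-1* was 16.5, 33.7 and 61.6 times as high in the control pairs and 16.5, 7.14 and 32.5 times in the starved pairs. The control EV libraries had 3, 1 and 3 reads of it.

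**Figure D1:**
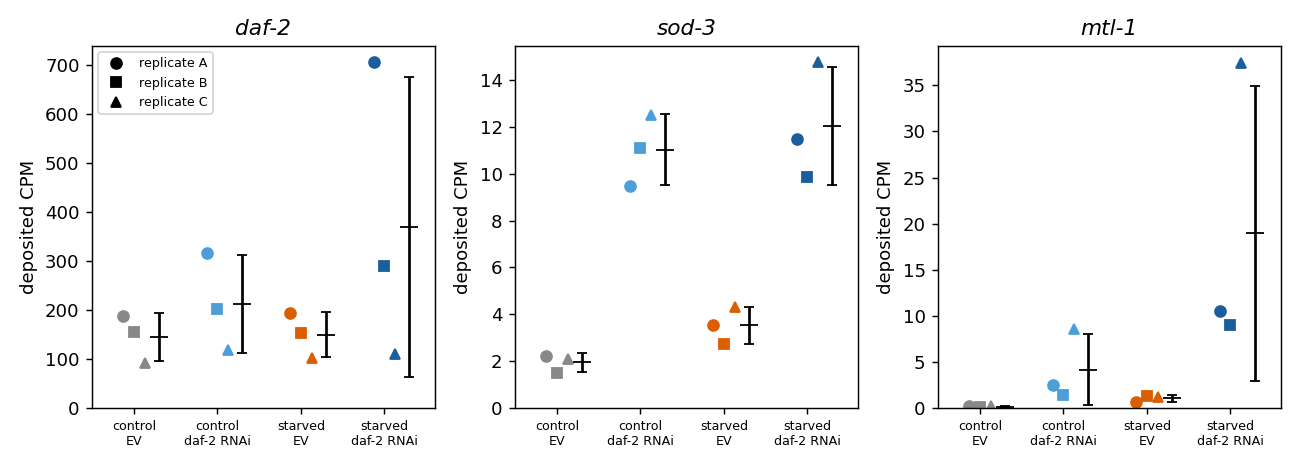
CPM of *daf-2*, *sod-3* and *mtl-1* in each of the 12 libraries, with the replicate letters as markers. *daf-2* reached 706 CPM in starved *daf-2* RNAi library A, and *sod-3* was higher in the library labelled *daf-2* RNAi in all 6 pairs.

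In a principal component analysis of all tested genes, the first component held 43.1% of the variance and set starved EV libraries (27.1 to 56.5) apart from all others (-31.8 to 9.38). The second component held 19.8% and ordered libraries by letter, with the A library highest in each group. The third held 17.5% and ran from -29.2 in control EV library A to 39.5 in starved *daf-2* RNAi library C.

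**Figure D2:**
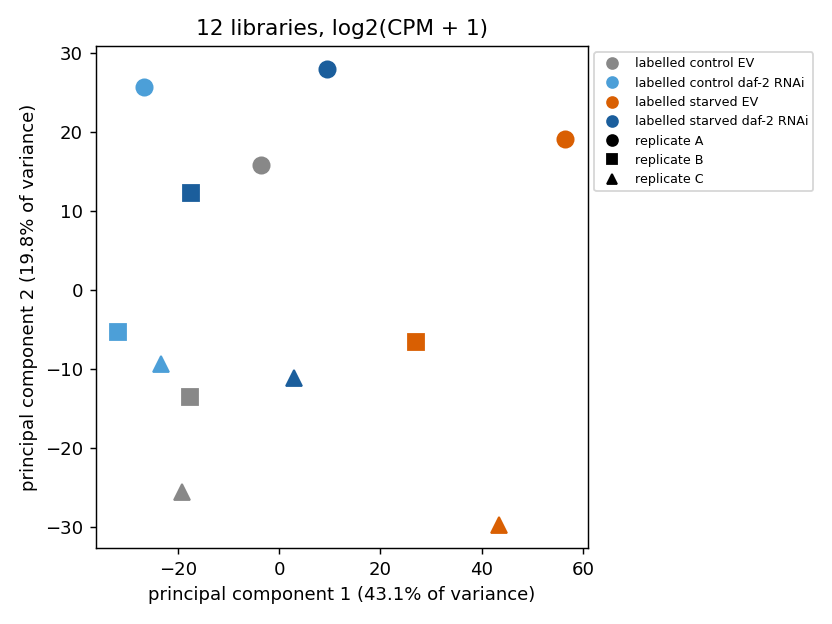
The 12 libraries on the leading principal components of log2(CPM + 1), with colour for the group and marker for the letter. Starved EV libraries lie apart on the first component, at 27.1 to 56.5, and starved *daf-2* RNAi libraries at -17.4 to 9.38.

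Starved EV against control EV libraries ask what 8 days of L1 arrest leave in the recovered adult. Of the 33 gene lists tested, 15 were called with camera's preset correlation and 0 with an estimated one. Among the 15 the list of the moulting cycle (median 1.19) was higher, and those of ribosomal proteins (-0.46) and germline identity (-0.43) were lower. The cuticlin gene *cut-2* (F53F1.5, V, 13414949 to 13416064) rose from 0.84 ± 0.82 to 74.7 ± 44.0 CPM, by 5.31 ± 0.42 (log2, SE; adjusted p = 1.14e-05). The collagen gene *col-165* (F14H12.1, X, 4353618 to 4354852) rose from 0.13 ± 0.11 to 31.2 ± 7.05 CPM, by 4.82 ± 0.21 (adjusted p = 1.30e-07). *glh-1* (T21G5.3, I, 6854478 to 6857536), which encodes a Vasa-like helicase of the germline P granules, fell from 616 ± 37.3 to 360 ± 57.1 CPM, by -0.78 ± 0.14 (adjusted p = 0.00452). In each of these genes all 3 libraries of one group lay above all 3 of the other, as the rule for named genes asks, which chance gives in 10% of genes.

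In all, limma called 2266 of the 12830 genes, 1481 higher and 785 lower in starved EV, and 573 rose and 7 fell by 2-fold or more. The letter as a block gave 6371 calls, all 2266 among them, with the balance turned to 2995 higher and 3376 lower. Calls numbered 897 (171 of them lower) without control EV library B, 728 (69 lower) without control EV C, 879 (151 lower) without starved EV A and 802 (87 lower) without starved EV C. DESeq2 on the recovered reads, which scales libraries by median ratios, gave 53.6% of its calls higher against 65.4% here. Among genes with a mean of at least 5 CPM the balance turned, with 626 higher and 709 lower (46.9% higher). Other large rises were the collagen genes *col-74* (4.40, adjusted p = 4.67e-07; 144 bases shared with an exon of *gtap-1*) and *col-107* (3.71, adjusted p = 9.72e-04), the linker histone gene *hil-7* (3.45, adjusted p = 0.0048), *tts-2* (4.59, adjusted p = 4.95e-06) and *chtb-1* (3.94, adjusted p = 8.91e-05). Falls were smaller: the collagen gene *col-139* changed by -2.22 (adjusted p = 0.0101), *lrg-1* by -0.95 (adjusted p = 0.00631) and *garr-1* from 330 ± 35.6 to 181 ± 10.0 CPM (adjusted p = 9.99e-04). *col-129* (-2.23) and *col-81* (-2.21) were no longer called without control EV B or starved EV C, where the adjusted p reached 0.0572 and 0.0661. Of 115 calls among the genes the rule names in this comparison, 58 held without each of the 12 libraries in turn.

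Of the 25 genes of the moulting cycle, 19 rose and none fell (19 higher and 1 lower adjusted over the list alone), with a median change of 1.19 (camera, adjusted p = 3.31e-08; adjusted p = 0.618 with an estimated correlation). Among them were the patched-related *ptr-4* (2.76, adjusted p = 1.52e-04), from 1.03 ± 0.69 to 12.4 ± 1.77 CPM, the hedgehog-related *wrt-1* (2.57, adjusted p = 6.12e-06) and *mlt-9* (2.56, adjusted p = 1.67e-05). Of 19 adult cuticle genes 7 rose (7 higher and 1 lower adjusted over the list alone; median 0.83, camera adjusted p = 0.0021, and adjusted p = 0.671 with an estimated correlation). Among them *sqt-3* rose from 17.7 ± 13.6 to 140 ± 37.6 CPM (3.20, adjusted p = 0.00628) and *dpy-7* from 3.07 ± 2.34 to 20.9 ± 3.86 (2.64, adjusted p = 0.00606). Of 93 collagens 26 rose and 6 fell (27 and 8 adjusted over the list alone; median 0.22, camera adjusted p = 0.0243, and adjusted p = 0.838 with an estimated correlation). The collagen list was not called without starved EV library A (adjusted p = 0.397) or control *daf-2* RNAi library A (0.0502), with array weights (0.124), or among genes with a mean of at least 5 CPM, where its median was -0.23 (0.329). The cuticle gene *dpy-14* (2.88, adjusted p = 0.0267) was not called without control EV B, control EV C, starved EV A or starved EV C, up to 0.092. *col-19*, an adult collagen gene, lay at 1975 ± 370 and 1268 ± 60 CPM (-0.62, adjusted p = 0.0727).

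Part of the markers of somatic tissues rose, and part of the germline genes fell. Pharynx markers rose in 8 of 17 genes (8 adjusted over the list alone; median 0.99, camera adjusted p = 4.31e-06, and adjusted p = 0.618 with an estimated correlation), with *abu-14* from 0.22 ± 0.15 to 21.8 ± 9.85 CPM and *phat-5* by 3.23 (adjusted p = 4.26e-06). Hypodermis markers rose in 6 of 13 (6 over the list alone; median 0.66, adjusted p = 0.0016, and adjusted p = 0.618 with an estimated correlation), led by the cuticlin gene *cut-3* (4.34, adjusted p = 1.47e-06). Neuron markers rose in 5 of 28, also adjusted over the list alone (median 0.46, adjusted p = 0.0017, and adjusted p = 0.76 with an estimated correlation), among them *rab-3*, a GTPase of synaptic vesicles (1.34, adjusted p = 0.00631). Intestine markers rose in 6 of 19, also adjusted over the list alone (median 0.35, adjusted p = 0.0098, and adjusted p = 0.697 with an estimated correlation), among them *pgp-1*, a P-glycoprotein, and the metallothionein gene *mtl-2* (2.27 and 1.17). None of 21 body muscle markers was called (median -0.09, or 0.09 after quantile normalization; adjusted p = 0.596). Without starved EV A the body muscle list was called lower (median -0.465, adjusted p = 0.024).

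Germline identity genes fell in 10 of 33 (19 adjusted over the list alone; median -0.43, camera adjusted p = 2.28e-09, and adjusted p = 0.618 with an estimated correlation). The P granule genes *pgl-1* and *pgl-2* changed by -0.74 (adjusted p = 0.00553) and -0.60 (adjusted p = 0.00834), the latter sharing 139 exon bases with *fli-1*. Oocyte and eggshell genes fell in 3 of 25 (none adjusted over the list alone; median -0.35, adjusted p = 0.0017, and adjusted p = 0.742 with an estimated correlation). Cell cycle genes fell in 4 of 31 and rose in 1 (7 and 2 over the list alone; median -0.34, adjusted p = 2.22e-04, and adjusted p = 0.697 with an estimated correlation). Ribosomal protein genes fell in 17 of 77 (35 adjusted over the list alone; median -0.46, camera adjusted p = 5.72e-14, and adjusted p = 0.681 with an estimated correlation), among them *rpl-25.2* (-0.70, adjusted p = 0.00563). Major sperm protein genes (15, none called, median -0.29, adjusted p = 0.152) and other sperm genes (11, none called, -0.02, 0.875) were not called. The major sperm protein list was called lower without control EV A (median -0.53, adjusted p = 0.0256), after quantile normalization (-0.62, 0.0078) and with array weights (-0.67, 0.004). After quantile normalization the cell cycle (-0.14, 0.207) and oocyte (-0.15, 0.414) lists were not called. The same scaling moved the medians of ribosomal protein genes to -0.19, adult cuticle genes to 0.45, hypodermis markers to 0.32, neuron markers to 0.28 and detoxification genes to 0.17.

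Defence and lipid genes rose in part. Innate immune genes rose in 11 of 32 (13 adjusted over the list alone; median 0.63, camera adjusted p = 2.02e-04, and adjusted p = 0.618 with an estimated correlation), with the lysozyme gene *lys-3* (1.66, adjusted p = 0.00149) and *cnc-2* (1.47, adjusted p = 0.00105). Detoxification genes rose in 9 of 34 (13 over the list alone; median 0.33, adjusted p = 0.0293, and adjusted p = 0.794 with an estimated correlation), with the cytochrome P450 gene *cyp-35C1* (0.87). That list was not called without control EV A (0.145) or starved EV C (0.0847) or with array weights (0.0509). Fatty acid oxidation genes rose in 5 of 31 and fell in 1 (9 and 1 over the list alone; median 0.31, adjusted p = 0.0186, and adjusted p = 0.618 with an estimated correlation), with *cpt-4* and *cpt-6*, carnitine palmitoyltransferase genes (1.35 and 0.73). Genes activated by DAF-16 rose in 5 of 18 (9 over the list alone; median 0.67, adjusted p = 0.0036, and adjusted p = 0.618 with an estimated correlation), with *dod-3* from 1.01 ± 0.54 to 6.95 ± 2.02 CPM and *nnt-1* from 1.54 ± 0.57 to 5.13 ± 1.32. Of 22 fatty acid synthesis and desaturation genes 2 rose (none adjusted over the list alone; median 0.11, adjusted p = 0.705, or 0.20 and 0.0159 after quantile normalization). They were the fatty acid synthase gene *fasn-1* (0.58, adjusted p = 0.0406) and the desaturase gene *fat-5* (1.02, adjusted p = 0.0325). The *fasn-1* call was lost without control EV B or C, control *daf-2* RNAi B or C, or starved EV A or C (up to 0.15), and the *fat-5* call without control EV A or B or starved EV A or C (up to 0.11). *pod-2* (0.11, adjusted p = 0.852), *fat-1* (0.28, adjusted p = 0.426) and *fat-6* (0.21, adjusted p = 0.638) were not called.

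Starved *daf-2* RNAi against starved EV libraries ask what the RNAi label changed after the long arrest. The saposin-like gene *spp-2* (T08A9.12, X, 7315995 to 7316818) rose from 9.88 ± 2.71 to 136 ± 32.3 CPM, by 3.66 ± 0.23 (log2, SE; adjusted p = 5.54e-06). *ugt-53* (T03D3.1, V, 2849343 to 2852028), a UDP-glucuronosyltransferase gene, fell from 33.4 ± 3.93 to 2.78 ± 0.39 CPM, by -3.18 ± 0.17 (adjusted p = 1.55e-06). Of the cuticle genes that were high in starved EV libraries, *cut-2* fell to 21.5 ± 6.31 CPM (-1.64, adjusted p = 0.0248), and *col-165* to 10.8 ± 1.61 CPM (-1.44, adjusted p = 0.0015). *glh-1* was higher, at 492 ± 19.5 CPM (0.46, adjusted p = 0.0466). The *cut-2* call was lost without starved EV A, starved *daf-2* RNAi B or starved *daf-2* RNAi C (up to adjusted p = 0.0845), and the *glh-1* call when any library other than control *daf-2* RNAi A or starved EV B was left out (up to 0.157).

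limma called 2017 genes, 488 higher and 1529 lower, of which 66 and 394 by 2-fold or more. Libraries of the same letter deviated together here. With the letter as a block 6151 genes were called, 3037 higher and 3114 lower, and all 2017 were among them. Of the calls 24.2% were higher, against 42.3% after quantile normalization and 40.1% with DESeq2. Calls numbered 801 (126 of them higher) without starved EV library A, 747 (95 higher) without starved EV C and 798 (217 higher) without starved *daf-2* RNAi B. Large rises included the ferritin gene *ftn-1* (2.57, adjusted p = 3.28e-04), the globin gene *glb-1* (1.58, adjusted p = 1.35e-04) and *asah-1*, an acid ceramidase gene (1.17, adjusted p = 3.42e-04). Large falls included the glycerol-3-phosphate dehydrogenase gene *gpdh-1* (-2.44, adjusted p = 0.0013), the C-type lectin gene *clec-10* (-2.04, adjusted p = 1.97e-04) and the acyl-CoA oxidase gene *acox-1.2* (-1.97, adjusted p = 5.02e-04). Of 139 calls among the genes the rule names here, 63 held without each of the 12 libraries in turn. *amt-1* (-1.95, adjusted p = 0.0129), for example, was lost without starved EV C or starved *daf-2* RNAi B, up to 0.0576.

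Genes activated by DAF-16 rose in 7 of 18 and fell in 1 (8 and 1 adjusted over the list alone; median 0.50, camera adjusted p = 4.73e-05, and adjusted p = 0.453 with an estimated correlation). *mtl-1* rose from 1.01 ± 0.33 to 18.95 ± 16.01 CPM (3.04, adjusted p = 0.00374), *nnt-1*, a nicotinamide nucleotide transhydrogenase gene, to 28.4 ± 5.59 (2.27, adjusted p = 2.61e-04) and *dod-3* to 33.5 ± 4.09 (2.14, adjusted p = 5.29e-04). *lys-7* (2.00, adjusted p = 0.0182) was not called without starved EV A (0.0665). Genes repressed by DAF-16 fell in 6 of 8, also adjusted over the list alone (median -1.21, adjusted p = 0.0012, and adjusted p = 0.618 with an estimated correlation), with *dod-24* (-1.96, adjusted p = 5.92e-04), *dod-23* (-1.96, adjusted p = 0.00464) and *dod-22* (-1.43, adjusted p = 0.00505). In the insulin pathway list 5 of 17 rose and 1 fell, also adjusted over the list alone, and 9 rose and 2 fell with the block (median 0.31, adjusted p = 0.0113, and adjusted p = 0.742 with an estimated correlation; 0.0671 without starved EV C and 0.0533 among genes with a mean of at least 5 CPM). The kinase gene *akt-1* rose from 173 ± 11 to 259 ± 25.3 CPM (0.58, adjusted p = 0.00612) and *sgk-1* fell from 28.5 ± 1.3 to 15.4 ± 0.54 CPM (-0.85, adjusted p = 0.00176).

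Moulting cycle genes fell in 11 of 25 (17 adjusted over the list alone; median -0.90, camera adjusted p = 2.32e-06, and adjusted p = 0.618 with an estimated correlation, or 0.0433 with the block as well), with *wrt-1* to 3.31 ± 0.37 CPM (-1.25, adjusted p = 0.00206). Collagens fell in 22 of 93 (24 over the list alone; median -0.50, adjusted p = 1.34e-06, and adjusted p = 0.76 with an estimated correlation), with *col-43* from 10.9 ± 4.18 to 1.21 ± 0.14 CPM (-2.37, adjusted p = 1.41e-04) and *col-74* (-1.35, adjusted p = 0.00385). Pharynx markers fell in 8 of 17, also over the list alone (median -0.68, adjusted p = 8.09e-04, and adjusted p = 0.697 with an estimated correlation; 0.0605 among genes with a mean of at least 5 CPM). Hypodermis markers fell in 6 of 13 (8 over the list alone; median -0.53, adjusted p = 0.0013, and adjusted p = 0.618 with an estimated correlation). Intestine markers fell in 9 of 19 and rose in 1 (11 and 1 over the list alone; median -0.66, adjusted p = 0.0013, and adjusted p = 0.618 with an estimated correlation), with *vha-6*, an intestinal proton pump subunit gene (-0.95, adjusted p = 0.00286). Adult cuticle genes fell in 5 of 19 (7 over the list alone) without a call for the list (median -0.13, or 0.045 after quantile normalization; adjusted p = 0.142). That list was called without starved EV C (-0.82, 0.0106), without starved *daf-2* RNAi A (-0.48, 0.0289) and among genes with a mean of at least 5 CPM (-1.297, 0.0063). With the letter as a block 19 moulting cycle genes fell and 1 rose, 36 collagens, 14 intestine markers and 9 hypodermis markers fell, and 3 intestine markers rose.

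Oocyte and eggshell genes rose in 11 of 25 (17 higher and 1 lower adjusted over the list alone; median 0.57, camera adjusted p = 1.60e-06, and adjusted p = 0.618 with an estimated correlation). *spn-4* went from 588 ± 76.6 to 898 ± 120 CPM (0.61, adjusted p = 0.017) and *oma-2* from 409 ± 67.2 to 617 ± 84.2 (0.59, adjusted p = 0.0212). Both calls were lost without starved EV A, starved EV C or starved *daf-2* RNAi B, up to 0.0766 and 0.0879. Germline identity genes rose in 11 of 33 (16 over the list alone; median 0.45, adjusted p = 1.22e-08, and adjusted p = 0.618 with an estimated correlation). *pgl-1* rose from 361 ± 56.6 to 524 ± 47.3 CPM (0.54, adjusted p = 0.0249; lost without starved EV A, starved EV C, starved *daf-2* RNAi A or starved *daf-2* RNAi B, up to 0.0942). Cell cycle genes rose in 6 of 31 and fell in 1 (11 and 2 over the list alone; median 0.36, adjusted p = 7.76e-06, and adjusted p = 0.64 with an estimated correlation). Under the block 22 oocyte, 29 germline and 26 cell cycle genes rose, and 1 oocyte and 2 cell cycle genes fell. Ribosomal protein genes fell in 2 of 77 with no call for the list (median -0.01, adjusted p = 0.675).

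In lipid metabolism, *fasn-1* fell from 481 ± 88.7 to 261 ± 38.8 CPM (-0.88, adjusted p = 0.00856), while *fat-5* rose from 68.1 ± 15.0 to 146 ± 36.7 CPM (1.08, adjusted p = 0.0279; lost without starved EV A or B or starved *daf-2* RNAi B or C, up to 0.0815). *fat-1* (-0.55, adjusted p = 0.137, or 0.0035 with the block) and *fat-3* (-0.51, adjusted p = 0.0668, or 0.0092) were called only with the block, and *fat-6* (-0.09, adjusted p = 0.846) in neither fit. The list of fatty acid synthesis and desaturation, with 1 higher and 2 lower of 22, was not called (median -0.28, adjusted p = 0.246, or 0.0189 after quantile normalization). Phosphatidylcholine and one-carbon genes fell in 3 of 19 (7 lower and 1 higher over the list alone; median -0.34, adjusted p = 0.0293, and adjusted p = 0.76 with an estimated correlation). The call of that list was lost without starved EV B (0.101), starved *daf-2* RNAi A (0.0571) or starved *daf-2* RNAi C (0.0527). Among them the S-adenosylmethionine synthetase gene *sams-1* fell from 506 ± 111 to 229 ± 41.9 CPM (-1.14, adjusted p = 0.00501), and the phosphoethanolamine methyltransferase gene *pmt-2* fell too (-1.12, adjusted p = 5.26e-04). The 6 vitellogenins, yolk protein genes, had a median of -0.92 and 1 called lower (adjusted p = 0.0907). The list was called without control EV A (0.0465), starved EV C (0.0094) or starved *daf-2* RNAi A (0.0407), and among genes with a mean of at least 5 CPM (0.037). With the letter as a block all 6 were lower and the list was called (adjusted p = 0.0015), 12 phosphatidylcholine genes and 10 genes of fatty acid synthesis and desaturation were lower, and 3 of each were higher. *vit-1* lay at 9411 ± 4817 and 3214 ± 1022 CPM (-1.47, adjusted p = 0.0485), and its call was lost when any library other than control EV A, control EV C, control *daf-2* RNAi A or starved EV C was left out (up to 0.141).

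Further lists were called with no called member, of which with the letter as a block body muscle markers had 16 of 21 lower, neuron markers 4 lower and 1 higher, and other sperm genes 1 higher. Major sperm protein genes had a median of 0.58 (adjusted p = 0.0089, and adjusted p = 0.802 with an estimated correlation), lost without starved *daf-2* RNAi C (0.431). Body muscle markers had a median of -0.55 (adjusted p = 0.0376, and adjusted p = 0.816 with an estimated correlation), lost without starved EV A (0.428), starved *daf-2* RNAi B (0.17) or starved *daf-2* RNAi C (0.185), or with array weights (0.284). Neuron markers had a median of -0.33 (adjusted p = 0.0296, and adjusted p = 0.816 with an estimated correlation), lost without starved EV A (0.339) or starved *daf-2* RNAi B (0.268), after quantile normalization (-0.12, 0.0693) or with array weights (0.204). Other sperm genes had a median of 0.41 (adjusted p = 0.0354, or 0.0946 with the block, and adjusted p = 0.76 with an estimated correlation), lost without starved EV B (0.105), starved EV C (0.0712), starved *daf-2* RNAi A (0.0739) or starved *daf-2* RNAi C (0.329), or among genes with a mean of at least 5 CPM (0.206).

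**Figure D3:**
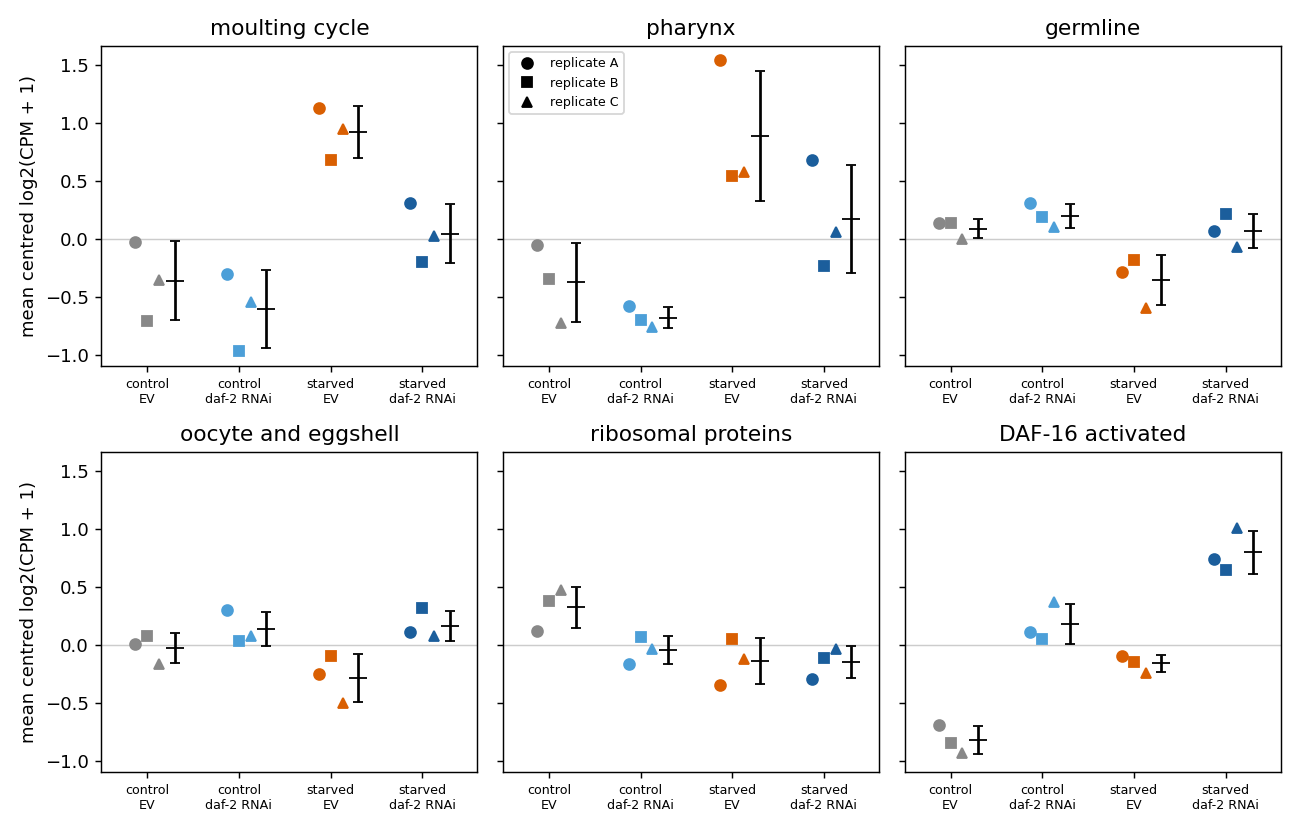
List scores of 6 gene lists (log2 units, mean of the members' deviations from their mean over the 12 libraries) in each library, with dash and bar for the mean ± SD of 3 libraries and markers for the letters. Moulting cycle scores lie between 0.68 and 1.13 in starved EV libraries and between -0.71 and -0.02 in control EV libraries.

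Control *daf-2* RNAi against control EV libraries ask what the label changed after a short arrest. *spp-2* rose from 8.55 ± 0.34 to 118.7 ± 28.2 CPM, by 3.62 (log2; adjusted p = 1.26e-05), *nnt-1* from 1.54 ± 0.57 to 18.3 ± 5.16 CPM (2.92, adjusted p = 6.63e-05), and *sod-3* by 2.04 ± 0.20 (adjusted p = 1.50e-04). *ugt-53* fell from 15.9 ± 2.55 to 3.01 ± 0.53 CPM (-2.08, adjusted p = 5.05e-05). *mtl-1* (1.95, adjusted p = 0.105, or 0.0091 with the letter as a block) lay at 0.11 ± 0.06 and 4.15 ± 3.89 CPM.

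limma called 178 genes, 85 higher and 93 lower, of which 57 and 43 by 2-fold or more. With the letter as a block 745 were called, 229 higher and 516 lower, and all 178 were among them. Of the calls 47.8% were higher, against 58.3% after quantile normalization. Calls numbered 91 (53 higher), 60 (39 higher) and 85 (46 higher) without control EV library A, B and C, and 116 and 75 without control *daf-2* RNAi B and C. Without control *daf-2* RNAi A 81 were higher and 38 lower. Rises included *dod-3* (2.52, adjusted p = 2.59e-04), *ftn-1* (2.1, adjusted p = 0.00258), *glb-1* (1.60, adjusted p = 1.29e-04) and *ges-1*, an intestinal esterase gene (1.08, adjusted p = 0.00145). Falls included *dod-24* (-1.78, adjusted p = 0.00286), *clec-10* (-1.70, adjusted p = 0.00129) and *ent-4* (-1.35, adjusted p = 0.00134). *lys-7* (2.67, adjusted p = 0.0153) was lost without control EV A, B or C or control *daf-2* RNAi C, up to 0.0775. *pud-3* (3.37, adjusted p = 0.0112) was lost without control EV B or control *daf-2* RNAi C, up to 0.0702. Of 39 calls among the genes the rule names here, 16 held without each of the 12 libraries. Of the 178 genes, 153 were called the same way in starved animals and 0 the opposite way, where independent calls would give 14.3 the same way.

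Genes activated by DAF-16 rose in 6 of 18 (8 adjusted over the list alone; median 0.44, camera adjusted p = 4.16e-13). The list was also called with an estimated correlation (adjusted p = 0.0417), and this call was lost with the letter as a block (0.238). Genes repressed by DAF-16 had 1 of 8 lower (4 over the list alone and 4 with the block; median -0.64, adjusted p = 9.48e-04, and adjusted p = 0.618 with an estimated correlation). Ribosomal protein genes had 2 of 77 lower, also over the list alone, and 44 lower with the block (median -0.36, adjusted p = 8.04e-19, and adjusted p = 0.618 with an estimated correlation). In the insulin pathway *akt-2* rose (0.92, adjusted p = 0.00351) and 1 gene fell (2 and 1 over the list alone, 3 and 1 with the block; median 0.18, adjusted p = 0.0037, and adjusted p = 0.697 with an estimated correlation). Among lipid genes *lipl-2*, a lysosomal lipase gene, rose (1.43, adjusted p = 0.00414). *fat-5* rose from 34.7 ± 15.9 to 106 ± 27.1 CPM (1.63, adjusted p = 0.014; lost without control EV A or B or control *daf-2* RNAi B or C, up to 0.0883). *fasn-1* was called only with the block (-0.34, adjusted p = 0.645, or 0.0497). Triglyceride and lipase genes rose in 2 of 19 (3 over the list alone and 4 with the block; median 0.09, adjusted p = 0.0073, and adjusted p = 0.707 with an estimated correlation). Phosphatidylcholine genes fell in 1 of 19 (4 with the block, among them *sams-1* at adjusted p = 0.0497; median -0.16, adjusted p = 0.0037, and adjusted p = 0.697 with an estimated correlation).

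Other lists were called with small medians and at most 1 called member each way. Oocyte genes had a median of 0.22 (adjusted p = 6.63e-04), cell cycle genes 0.13 (0.0037), germline genes 0.13 (0.0046), glyoxylate and trehalose genes 0.23 (0.0062), collagens -0.22 (0.0037), body muscle markers -0.39 (0.0056) and intestine markers -0.31 (0.0293). With an estimated correlation their adjusted p values were 0.707, 0.742, 0.76, 0.618, 0.833, 0.76 and 0.742. In the blocked fit 4 glyoxylate and trehalose genes rose, 2 intestine markers rose and 4 fell, 1 collagen rose and 2 fell, and 1 gene each of the cell cycle, embryonic and vitellogenin lists fell. Many of these calls rest on 1 library. Without control *daf-2* RNAi library A the oocyte (0.063), cell cycle (0.195), germline (0.162), collagen (0.0934), intestine (0.0701), phosphatidylcholine (0.0828), insulin pathway (0.0761) and neuron (0.493) lists were not called. Without control *daf-2* RNAi B the embryonic list (0.557) was not called, and without control *daf-2* RNAi C neither the body muscle (0.0814), the intestine (0.0634) nor the triglyceride list (0.0958). Without control EV A the body muscle (0.197), intestine (0.409), neuron (0.111), embryonic (0.36) and triglyceride (0.0791) lists were not called. Without control EV B this held for the neuron (0.22) and phosphatidylcholine (0.0655) lists, and without control EV C the glyoxylate (0.0844), insulin pathway (0.0626) and embryonic (0.0518) lists. Embryonic genes (-0.23, adjusted p = 0.0323, or 0.0927 with the block, and adjusted p = 0.742 with an estimated correlation) and neuron markers (-0.20, adjusted p = 0.0389, or 0.0787 with the block, and adjusted p = 0.816 with an estimated correlation) were called without the block, and vitellogenins (adjusted p = 0.385, or 0.045) with it. With array weights the oocyte (0.148), cell cycle (0.0638), germline (0.132), glyoxylate (0.0655), intestine (0.0695) and embryonic (0.424) lists were not called. After quantile normalization the embryonic (0.0522) and neuron (0.0504) lists were not called, and the medians were -0.19 for ribosomal protein genes, -0.11 for collagens and -0.20 for intestine markers. Among genes with a mean of at least 5 CPM the triglyceride list was not called (-0.02, 0.941). Moulting cycle genes were not called (median -0.20, adjusted p = 0.173, none of 25 called). Without control EV B or control *daf-2* RNAi A the lists of moulting cycle (0.0025 and 0.0044), adult cuticle (0.0056 and 0.0197) and hypodermis genes (0.0254 and 0.0264) were called lower. Without control EV C those of the pharynx (0.0237) and the vitellogenins (0.0263) were.

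Starved *daf-2* RNAi against control *daf-2* RNAi libraries ask what the long arrest leaves under the RNAi label. Single genes of the cuticle and the pharynx were among the rises. *col-165* rose from 0.39 ± 0.29 to 10.8 ± 1.61 CPM (3.09, adjusted p = 2.80e-05), *cut-3* from 0.35 ± 0.31 to 8.44 ± 2.87 (2.78, adjusted p = 2.80e-04), *abu-14* from 0.47 ± 0.32 to 6.27 ± 2.30 (2.29, adjusted p = 0.00286) and *tts-1*, a long non-coding RNA, from 46.6 ± 11.9 to 240 ± 109 (2.29, adjusted p = 0.00201). limma called 90 genes (481 with the letter as a block), 85 higher and 5 lower, of which 74 and 1 by 2-fold or more. Calls numbered 56 and 49 without control EV B and C, 28 and 42 without control *daf-2* RNAi B and C, 136 without starved EV A, and 34, 195 and 41 without starved *daf-2* RNAi A, B and C. Without control *daf-2* RNAi A 62 were higher and 20 lower. Of 22 calls among the genes named here, 10 held without each library.

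Moulting cycle genes rose in 4 of 25 (7 higher and 1 lower adjusted over the list alone; median 0.73, camera adjusted p = 1.50e-06, and adjusted p = 0.618 with an estimated correlation), with *mlt-9* by 1.57 (adjusted p = 0.00346). Pharynx markers rose in 3 of 17 (6 over the list alone; median 0.74, adjusted p = 4.33e-08, and adjusted p = 0.618 with an estimated correlation), with *phat-5* by 2.22 (adjusted p = 4.80e-04). Adult cuticle genes had none called among all genes but 9 higher and 1 lower over the list alone (median 0.78, adjusted p = 2.20e-06, and adjusted p = 0.618 with an estimated correlation). Genes activated by DAF-16 rose in 2 of 18 (5 over the list alone; median 0.44, adjusted p = 1.59e-05, and adjusted p = 0.453 with an estimated correlation). Innate immune genes rose in 3 of 32 (5 over the list alone; median 0.28, adjusted p = 2.01e-04, and adjusted p = 0.618 with an estimated correlation). Hypodermis markers rose in 1 of 13 (3 over the list alone; median 0.43, adjusted p = 0.0178, and adjusted p = 0.618 with an estimated correlation). With no called member, germline genes had a median of -0.13 (adjusted p = 5.70e-04; 0.0918 without control *daf-2* RNAi A), ribosomal protein genes -0.10 (0.0013; 0.179 without starved *daf-2* RNAi A), phosphatidylcholine genes -0.15 (0.0017), neuron markers 0.32 (1.28e-04) and other sperm genes 0.44 (0.0296). With an estimated correlation their adjusted p values were 0.742, 0.816, 0.697, 0.742 and 0.76, and the other sperm list was lost without control *daf-2* RNAi A (0.0984), starved *daf-2* RNAi A (0.0527) or starved *daf-2* RNAi C (0.553), with array weights (0.0638), or among genes with a mean of at least 5 CPM (0.0943). After quantile normalization the germline (median -0.065, 0.204) and ribosomal protein (-0.001, 0.656) lists were not called, and the medians of other sperm genes and hypodermis markers were 0.26 and 0.22. The ribosomal protein list was also not called among genes with a mean of at least 5 CPM (0.054). Collagens, with 5 higher and 2 lower of 93 (23 and 26 over the list alone), were not called as a list (median 0.25, adjusted p = 0.791). That list was called higher without starved *daf-2* RNAi C (0.34, 0.0284) and lower among genes with a mean of at least 5 CPM (-0.59, 0.013).

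Starved *daf-2* RNAi against control EV libraries compare the animals that differ in both factors. *tts-1* rose from 11.9 ± 2.49 to 240 ± 109 CPM (4.16, adjusted p = 4.61e-06), *dod-3* from 1.01 ± 0.54 to 33.5 ± 4.09 (4.14, adjusted p = 2.60e-06) and *nnt-1* to 28.4 ± 5.59 (3.54, adjusted p = 4.61e-06). *sams-1* fell from 500 ± 62.1 to 229 ± 41.9 CPM (-1.13, adjusted p = 0.00525) and *col-19* from 1975 ± 370 to 738 ± 80.8 (-1.41, adjusted p = 0.00268). limma called 741 genes, 407 higher and 334 lower. Calls numbered 389 and 451 without control EV B and C and 460 without starved *daf-2* RNAi C, and 648 were higher and 253 lower without starved *daf-2* RNAi B. The balance turned after quantile normalization (379 higher and 442 lower), among genes with a mean of at least 5 CPM (171 and 249), with array weights (799 and 1051) and without control *daf-2* RNAi A (416 and 421). Genes activated by DAF-16 rose in 10 of 18 (13 higher and 1 lower adjusted over the list alone; median 1.02, camera adjusted p = 5.16e-13, and adjusted p = 0.0417 with an estimated correlation). Ribosomal protein genes fell in 2 of 77 (39 over the list alone; median -0.47, adjusted p = 5.54e-20, and adjusted p = 0.618 with an estimated correlation). Phosphatidylcholine genes fell in 4 of 19 (9 over the list alone; median -0.35, adjusted p = 2.53e-05, and adjusted p = 0.618 with an estimated correlation). Moulting cycle genes rose in 5 of 25 and fell in 1 (7 and 2 over the list alone; median 0.29, adjusted p = 0.0062, and adjusted p = 0.76 with an estimated correlation), with 0.0961 without control EV B and 0.0709 without starved *daf-2* RNAi A. Germline genes were not called (none of 33, median -0.03, or 0.075 after quantile normalization; adjusted p = 0.652). Of 84 calls among the named genes in this comparison, 58 held without each library.

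Further lists passed in this comparison. Innate immune genes rose in 6 of 32 (9 higher and 1 lower over the list alone; median 0.22, adjusted p = 0.0013, and adjusted p = 0.697 with an estimated correlation), pharynx markers in 5 of 17, also over the list alone (0.28, 0.0048 and 0.742), and triglyceride and lipase genes in 5 of 19, also over the list alone (0.05, 0.0204 and 0.742). Adult cuticle genes had 1 higher and 1 lower (0.74, 0.0072 and 0.697). Body muscle markers fell in 1 of 21 (3 over the list alone; -0.65, 0.0013 and 0.742), propionate genes in 3 of 11 (5 over the list alone; -0.37, 0.0135 and 0.618) and genes repressed by DAF-16 in 3 of 8, also over the list alone (-0.46, 0.0085 and 0.697). Glyoxylate and trehalose genes (0.29, 0.026 and 0.618), oocyte genes (0.20, 0.0188 and 0.77) and other sperm genes (0.59, 0.017 and 0.742) had no called member, and the insulin pathway had 2 higher and 1 lower (0.20, 0.0441 and 0.76). Without control EV A the sperm (0.0554) and triglyceride (0.113) lists were not called. Without control EV B the insulin pathway (0.0527) was not called, without control EV C the glyoxylate (0.0844), insulin pathway (0.147) and oocyte (0.0907) lists, and without control *daf-2* RNAi B the insulin pathway (0.0501). Without starved *daf-2* RNAi A the adult cuticle (0.105), pharynx (0.0658), glyoxylate (0.0527) and insulin pathway (0.095) lists were not called. Without starved *daf-2* RNAi B the same held for genes repressed by DAF-16 (0.0534), glyoxylate (0.0534), insulin pathway (0.299) and oocyte genes (0.321), and without starved *daf-2* RNAi C for propionate (0.0527), sperm (0.26) and triglyceride genes (0.134). Among genes with a mean of at least 5 CPM the moulting cycle (0.518), adult cuticle (0.0887), pharynx (0.108), sperm (0.107) and triglyceride (median -0.06, 0.865) lists were not called. With array weights the glyoxylate (0.108), oocyte (0.165), sperm (0.125) and triglyceride (-0.06, 0.148) lists were not called. After quantile normalization the propionate list was not called (-0.15, 0.196), and the medians of ribosomal protein, oocyte and triglyceride genes were -0.18, 0.36 and 0.11. With median-of-ratios scaling the insulin pathway was not called (0.0533).

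Whether the change after long arrest differed between EV and *daf-2* RNAi was tested as an interaction. No single gene passed in limma (0 of 12830, smallest adjusted p = 0.297, 912 genes at an unadjusted p under 0.05). edgeR called 0 and DESeq2 4, and limma with the letter as a block called 63, 6 higher and 57 lower. A fit with this block within each arrest length, added after the data were seen, called 770, 224 higher and 546 lower. Among the 2266 genes called after long arrest on EV, 467 of these differences were opposite in sign to the change on EV and 0 the same, which the choice of genes by their change on EV favours. *col-165* had a difference of -1.73 and *wrt-1* of -1.56 (both adjusted p = 0.297, or 0.0136 and 0.023 with the block), and *abu-14* and *cut-3* of -1.86 and -1.56 (both adjusted p = 0.308, or 0.0219 and 0.0281). As lists, moulting cycle genes rose less on *daf-2* RNAi than on EV (median difference -0.67, camera adjusted p = 6.65e-07, and adjusted p = 0.618 with an estimated correlation, or 0.0433 with the block as well), and germline genes fell less (0.31, adjusted p = 9.51e-08, and adjusted p = 0.618 with an estimated correlation). In all 12 lists passed with the preset correlation and 0 with an estimated one (1 with the block, the moulting cycle genes), and fry passed 0. With the letter as a block vitellogenins (adjusted p = 0.153, or 0.0019), genes repressed by DAF-16 (0.0525, or 0.0106), innate immune genes (0.0504, or 0.0017) and fatty acid synthesis genes (0.182, or 0.0372) passed too. Of these, the last 3 passed after quantile normalization as well (0.04, 0.0366 and 0.0109).

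Genes called after long arrest on EV had smaller median changes on *daf-2* RNAi, and being chosen for their change on EV favours that. The 1481 genes higher in starved EV had a median change of 0.88 on EV and 0.41 on *daf-2* RNAi, with the same sign in 94.6%, and the 785 lower genes -0.49 and -0.20, with the same sign in 97.3%. Of the 2266 genes, 813 (35.9%) were called in the opposite direction between starved *daf-2* RNAi and starved EV libraries, and 42 in the same direction, where independent calls would give 149.9 in the same direction. Of these 813, 655 were higher and then lower (176.5 for independent calls), among them *cut-2*, and 158 lower and then higher (29.9), among them *glh-1*. Both comparisons use the starved EV libraries, which favours opposite calls. The 813 became 386 and 366 without control EV B and C, 541 without control *daf-2* RNAi C, 212 and 203 without starved EV A and C, and 244 (10.7%) without starved *daf-2* RNAi B. In the fit with the block within each arrest length 1749 of the 2266 (77.2%) were called the opposite way between the starved groups and 70 the same way. Of the 2266 genes 285 were called the same way between starved *daf-2* RNAi and control EV.

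The 4 relations between effects run across the 12830 genes, which are not independent replicates, and no p is given. The starvation effect on EV and on *daf-2* RNAi, which share no library, had a Pearson r of 0.73 (Spearman's rho 0.66). The RNAi effect in control and in starved animals had 0.67 (0.64). Simulations without effects gave values near 0, but they drew the noise of each library independently. Same-lettered EV and *daf-2* RNAi libraries of an arrest length deviated together. That alone would raise the r of the starvation effects, so a value near 0 is no benchmark for it. The average starvation effect and the average RNAi effect had r = -0.32 (rho -0.42), but -0.187 with array weights, -0.198 with DESeq2 and -0.201 with edgeR. Simulations without effects gave 0.002, which follows from the equal spread they gave all groups and so is no test of chance. The starvation effect on EV and the RNAi effect in starved animals had r = -0.62 (rho -0.68), and -0.501 with DESeq2, but the shared starved EV libraries alone gave -0.50 in simulations. Their covariance was -0.153, against -0.024 in simulations.

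**Figure D4:**
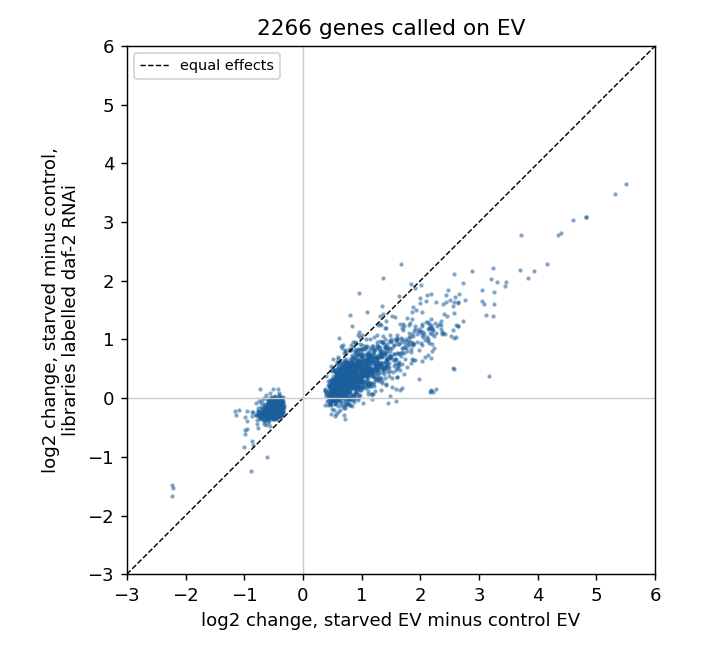
Log2 change after long arrest on EV (horizontal axis) and on *daf-2* RNAi (vertical axis) for the 2266 genes called on EV, with a dashed line where both are equal. Most points lie between the horizontal axis and the dashed line, with medians of 0.88 and 0.41 among the genes higher in starved EV.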

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

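Of the tests in this part, those on the germline share, on embryos or larvae, on single letters and on exchanged libraries or bacterial RNA were chosen only after the result was seen, as were all counts of splits. The following lists were singled out because the change after long arrest differed between EV and *daf-2* RNAi in camera with a preset correlation. In the main fit no list passed with an estimated correlation and no single gene in limma. With the letter as a block the moulting cycle genes passed with an estimated correlation (adjusted p = 0.0433). In limma 63 genes then passed, or 770 with the block within each arrest length. Values are median log2 differences, the change on *daf-2* RNAi minus that on EV.

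Lower on *daf-2* RNAi relative to EV were the moulting cycle genes (-0.673, adjusted p = 6.65e-07, and adjusted p = 0.618 with an estimated correlation), collagens (-0.349, 9.17e-05 and 0.798), hypodermis markers (-0.343, 0.0028 and 0.618), intestine markers (-0.315, 0.0013 and 0.618), pharynx markers (-0.308, 0.0017 and 0.707), fatty acid oxidation genes (-0.181, 0.0082 and 0.618) and detoxification genes (-0.112, 0.0184 and 0.76). Higher were the major sperm protein genes (0.651, adjusted p = 0.0012, and 0.76 with an estimated correlation), ribosomal protein genes (0.364, 1.4e-13 and 0.682), oocyte and eggshell genes (0.346, 1.04e-04 and 0.697), germline identity genes (0.312, 9.51e-08 and 0.618) and cell cycle genes (0.24, 3.56e-04 and 0.701). The collagen call was lost without starved EV A, where the median was 0.028 (adjusted p = 0.304), and without starved *daf-2* RNAi C (0.0606). The detoxification call was lost without control EV A (0.145), control *daf-2* RNAi B (0.146), starved EV C (0.0793) or starved *daf-2* RNAi A (0.112), and the sperm protein call without starved *daf-2* RNAi C (0.269). The pharynx call was lost with array weights (0.0682) and among genes with a mean of at least 5 CPM (median 0.09, 0.324). After quantile normalization the medians of ribosomal protein, oocyte and detoxification genes were 0.20, 0.22 and -0.07.

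Of 25 moulting cycle genes 19, and of 19 adult cuticle list genes 7, were higher in starved EV than in control EV libraries. A lower germline share would raise all somatic lists alike. The moulting score rose by 1.27 more than body muscle (95% interval 0.43 to 2.12), but about as pharynx did (1.28 and 1.26). Body muscle's own interval was -1.05 to 1.06, so this decides nothing. No letter alone carries the rise, since the moulting median was at least 1.16 with any left out. Animals still in the L4 moult may contribute: 5 collagens of that stage had a median of 0.81, over the 0.6 set for this test, with none called, and the interval of their mean, -0.77 to 2.51, leaves this open. Late embryos or young larvae may too. Median and mean of 8 early-life regulators were 0.52 and 0.75 (0.41 to 1.08), around the 0.6. Only *hbl-1* was called (2.64, adjusted p = 0.0029, picked after its value was seen). The embryonic list fixed before had a mean of 0.21 (-0.07 to 0.49), under 0.6. These causes and arrest itself cannot be told apart, as recovery time follows arrest length.

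The CPM of *daf-2* was higher in the library labelled *daf-2* RNAi in each pair, by a ratio of only 1.08 in starved pair C. Lower insulin signalling raises *sod-3*, so a pair with exchanged RNAi and EV labels would have it lower in the library labelled RNAi, and RNAi without effect would leave it higher in about as many pairs as lower. It was higher in the library labelled RNAi in 6 of 6 pairs, which argues against both. Reads from the double-stranded RNA made by the bacteria are a candidate source: the highest ratio was 3.65, in starved pair A, but the deposited values hold no positions along the gene, so this cannot be told apart from a higher transcript level. No biological explanation was tested.

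The change after long arrest was smaller on *daf-2* RNAi than on EV for genes called on EV. Chance inflation alone would leave a ratio near equality in libraries not used for picking. For each letter, 500 genes were picked on EV without it. In that letter the *daf-2* RNAi change was 0.52, 0.421 and 0.462 times that on EV (A, B and C). Picking on EV only still favours larger changes there, so selection stays open. Part of the 813 opposite calls between long arrest and RNAi may come from the starved EV libraries shared by both. The average effects had r = -0.32, but only -0.187 with array weights, -0.198 with DESeq2 and -0.201 with edgeR. They share no chance values only if all groups have the same spread, which the simulations without effects (0.002) assumed. That *daf-2* RNAi during recovery lessens the change left by long arrest is a hypothesis, found and examined on the same libraries.

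Other splits of the same libraries were refitted. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real counts were 2266 (starved EV against control EV), 2017 (starved *daf-2* RNAi against starved EV), 178 (control *daf-2* RNAi against control EV), 90 (starved against control *daf-2* RNAi) and 741 (starved *daf-2* RNAi against control EV), and the highest other count was 0 in each. For the interaction the real count was 0, which every split reaches, so that 100 of 100 splits of the 12 libraries did so decides nothing. The highest other count, 1521, points to the structure of the samples, since random groups mix the real ones.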

How the results depend on the processing

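The block within each arrest length, leaving out whole letters, and list tests with a pseudocount of 0.25, other filters, quantile normalization or array weights were chosen after the data were seen. Of 1518 results for named genes 399 were called; 312 of these lost the call under at least 1 alternative and 0 reversed. Of 198 list results 84 were called, and 45 of these lost the call under at least 1 alternative or left-out library, an estimated correlation and fry not counted. Lists were not tested in fits of the compared groups alone, edgeR or DESeq2. In comparison 4, 3 list results reversed: collagens to -0.594 (called lower) with a mean of at least 5 CPM, and after quantile normalization oocyte genes to 0.083 (called higher) and ribosomal protein genes in camera's direction, without a call, at a median of -0.001. Counts are given in the order starved EV against control EV (1), starved *daf-2* RNAi against starved EV (2), control *daf-2* RNAi against control EV (3), starved against control *daf-2* RNAi (4), starved *daf-2* RNAi against control EV (5) and the interaction (6). Counts not given stayed within 1.5 times, and the cause was not tested unless named. A pseudocount of 4 gave 50 in comparison 4 and 1 in 6. A mean of at least 5 CPM, which tests fewer genes, gave 1335, 1329, 16 and 420 in 1, 2, 4 and 5, with 415 genes moved back by RNAi and 26 moved further. Quantile normalization gave 1484 and 54 in 1 and 4, with 23 moved further, and moved the median of all genes in comparison 1 from 0.025 to -0.075. With the replicate block the counts were 6371, 6151, 745, 481, 2236 and 63, with 3939 genes (61.8%) moved back and 145 further, and the balance turned to 2995 higher and 3376 lower in 1 and to 973 and 1263 in 5. Across arrest lengths letters A and C correlated and letter B did not (0.645, 0.085 and 0.659 for A, B and C in comparison 1, 0.487, -0.095 and 0.579 in 4, and 0.671, -0.141 and 0.409 in 5). Each of the 12 libraries correlated best with its own letter among the libraries of other groups. With the preset correlation the block changed these list calls: vitellogenins to 0.0224 and detoxification to 0.0535 in comparison 1, other sperm genes to 0.0626 in comparison 4, and those printed in the report; it changed no other list call with the preset correlation and ended no call of a named gene, while it added calls of named genes. Within arrest length it gave 7397, 1504 and 770 in 2, 3 and 6. Fits of the compared groups alone gave 1124 (1034 higher), 1035, 91 (51 higher) and 45 in 1 to 4, with 329 moved back and 26 further. Array weights gave 3635, 1163, 1178, 285 and 1850 in 1 to 5, correlations of -0.187 between average effects and 0.525 between RNAi effects, and 518 genes (14.3%) moved back. edgeR gave correlations of -0.201 between average effects and -0.506 between the starvation effect on EV and the RNAi effect in starved animals. DESeq2 gave 383, 372, 1296 and 4 in 3 to 6, correlations of -0.198 and -0.501, and 72 genes moved further.

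With an estimated correlation 0, 0, 1, 0, 1 and 0 lists passed in comparisons 1 to 6. With the block as well, moulting cycle genes passed in 1, 2, 4 and 6 (adjusted p = 0.0433 in each), and genes activated by DAF-16 lost the call in 3 and 5 (0.238 in each). In the fit without the block fry passed 10, 1, 3, 4 and 0 in 2 to 6, against 15, 16, 15, 11, 15 and 12 with the preset correlation. Array weights passed 9 in comparison 3. Leaving out libraries, singly or by letter, gave 174 to 2623, 160 to 2147, 15 to 180, 5 to 195, 192 to 901 and 0 to 1 genes in comparisons 1 to 6. Genes moved back ranged from 12 to 1096 (6.9% to 50.3%) and moved further from 4 to 44. Correlations ranged from -0.404 to -0.218 between average effects, from -0.694 to -0.508 between the starvation effect on EV and the RNAi effect in starved animals, from 0.629 to 0.741 between starvation effects and from 0.545 to 0.702 between RNAi effects. Lists passed in 14 to 17, 13 to 17, 10 to 17, 10 to 14, 11 to 15 and 12 to 16 cases. Without all libraries of letter A, B or C comparison 1 gave 952, 670 and 174 and comparison 2 gave 888, 165 and 160, with 2 libraries left per group. The balance of comparison 3 also turned without starved EV B (73 higher and 68 lower) and without letter A, B or C (22 and 6, 11 and 4, and 36 and 20), and that of comparison 5 without letter A (263 and 400). Depth was 21150912 to 30037731 reads, and with 3 libraries per group a simulated change of 1.5 times was called in 11.9% of genes in comparison 1.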

Other observations

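The gene class tests and the grouping of classes in this part were chosen only after the data were seen; the gene lists were fixed before.

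Beyond the genes of the report, part of the genes of some classes were lower in starved EV than in control EV libraries, and no class passed with an estimated correlation. Of the mitochondrial ribosomal protein genes, 11 of 39 mrpl genes fell (median -0.43, camera adjusted p = 8.20e-10) and 11 of 28 mrps genes (-0.44, adjusted p = 8.40e-09), beside 13 of 45 rpl genes and 7 of 24 translation initiation factor genes of the eif class (-0.35, adjusted p = 4.11e-06). Higher were 28 of 166 nuclear hormone receptor genes (nhr, median 0.35, adjusted p = 6.86e-08), 14 of 18 cuticlin-like genes (cutl, 0.94, adjusted p = 1.29e-07), 15 of 22 patched-related genes (ptr, 0.88, adjusted p = 5.76e-08), 20 of 54 cytochrome P450 genes (cyp, 0.43, adjusted p = 1.04e-05) and 17 of 54 ugt genes (0.38, adjusted p = 3.21e-05). Between starved *daf-2* RNAi and starved EV, 22 ugt genes fell (median -0.49, adjusted p = 8.30e-09), as did 35 nhr genes (-0.37, adjusted p = 6.82e-08), 11 cutl genes (-0.79, adjusted p = 1.55e-06) and 9 of 20 proton pump genes of the vha class (-0.45, adjusted p = 1.93e-04). In all 48 of 116 classes passed in starved EV against control EV with the preset correlation, and 0 with an estimated one (adjusted p = 0.856 for each class named), so members of a class may move together. In the other comparisons 39 (starved *daf-2* RNAi against starved EV), 21 (control) and 26 (starved against control *daf-2* RNAi) passed, and 0 with an estimated correlation.

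Of 26 Wnt pathway genes 6 were higher in starved EV than in control EV (8 higher and 1 lower adjusted over the list alone; list not called, median 0.23, adjusted p = 0.279, or 0.0182 after quantile normalization), among them the Wnt ligand genes *egl-20* (0.88, adjusted p = 0.0165; lost without control EV C, starved EV A or starved EV C, up to 0.0741) and *cwn-2* (0.84, adjusted p = 0.0222; lost without control EV B, starved EV A or starved EV C, up to 0.0794). Between starved *daf-2* RNAi and starved EV 5 Wnt pathway genes fell, among them the Frizzled gene *mig-1* (-0.77, adjusted p = 0.00682), and 1 rose. Of 15 insulin-like peptide genes *ins-23* (1.31, adjusted p = 0.00168) and *ins-35* (1.08, adjusted p = 0.015) rose and *ins-2* (-0.97, adjusted p = 0.0302) and *ins-7* (-0.85, adjusted p = 0.0417) fell in that comparison. The *ins-2* call was lost without starved EV A, B or C or starved *daf-2* RNAi B or C (up to 0.105), the *ins-7* call without control EV B or C, control *daf-2* RNAi B, starved EV B or C, or starved *daf-2* RNAi A or B (up to 0.149), and the list was not called (median -0.24, or 0.016 after quantile normalization; adjusted p = 0.715). Propionate genes fell in 4 of 11 without a call for the list (6 lower and 1 higher with the letter as a block; median -0.27, adjusted p = 0.0535). That list was called without starved EV C (0.0157), starved *daf-2* RNAi A (0.0463) or starved *daf-2* RNAi B (0.0323), after quantile normalization (0.0026), with a pseudocount of 0.25 (0.0463) and among genes with a mean of at least 5 CPM (0.0136). Members that fell include *hphd-1* (-1.04, adjusted p = 5.99e-04) and *hach-1* (-0.84, adjusted p = 0.00464). The lysosomal lipase genes *lipl-1* (1.06, adjusted p = 6.49e-04) and *lipl-2* (1.19, adjusted p = 0.00445) rose, while triglyceride and lipase genes as a list, with 5 higher and 2 lower of 19 (8 and 7 with the letter as a block), were not called (median 0.19).

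Lists not called in starved EV against control EV included the insulin pathway (17 genes, median -0.19, adjusted p = 0.479), insulin-like peptides (0.04, adjusted p = 0.599), triglyceride and lipase genes (3 of 19 higher, 0.27, adjusted p = 0.13), chaperones (25 genes, -0.05, adjusted p = 0.595), embryonic genes (18, 0.25, adjusted p = 0.203), somatic gonad genes (16, 0.33, adjusted p = 0.203), replication histones (15, 0.01, adjusted p = 0.738) and reference genes (16, -0.24, adjusted p = 0.103). Of these, the triglyceride list was called without starved EV A (0.0339) and after quantile normalization (0.0107), the reference genes without control EV C (0.0299) or starved EV A (0.0176), and the embryonic genes with array weights (0.0376). The 3 ribosomal RNA genes were not tested as a list. The A library had the highest body muscle score and the highest vitellogenin score of its group in all 4 groups.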
